A study of Mus musculus with 8 samples.

How the data were processed

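Whole spines of E18.5 mouse embryos were profiled by mRNA sequencing in 8 libraries, 2 each from male wild type (WT), male knockout (KO), female WT and female KO. KO stands for the Pax1-Enh knockout named in the labels. Per the labels' protocols, frozen spines were crushed and homogenised, RNA was extracted with TRIzol, and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. The authors deposited one table of whole-number read counts per gene for the 8 libraries, with no normalization, and these counts are the unit used throughout. FastQC, MultiQC, HISAT2, featureCounts and the mm10 build are named in the submitters' processing notes, which give no order or settings. The gene annotation, the strand setting of the counting and the treatment of reads that match more than 1 place are not given in the sources used here, and neither are the coordinates of the deleted region.

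The table holds 27179 genes by Entrez gene ID. Of these, 25275 took a symbol from a RefSeq table of the GRCm38.p6 assembly (the mm10 build), 18 more from GENCODE release M21, and 1886 stayed without a name. The genes without a name carried 0.365% to 1.63% of the counts of a library. Library totals ran from 35181518 to 67575728 counts. All 4 KO libraries were deeper (59722279 to 67575728 counts) than all 4 WT libraries (35181518 to 48021848 counts), so depth and genotype cannot be separated by design. A count of 3 corresponds to 0.0392 to 0.0831 CPM, edgeR's unit of counts scaled to the TMM-normalised library size. Counting intervals cover counting error only. Every column of the table belonged to a sample of the series, and none was left out.

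The labels number the replicates 1 and 2 in each group and do not say whether these came from separate embryos, so the p-values measure the spread between these samples. Counts of the paired libraries within a group differed beyond sampling noise (chi-square per degree of freedom 131 in female WT, 158 in male WT, 417 in female KO and 645 in male KO), and all 8 were kept as separate samples. Their Spearman correlations across genes, which are not independent replicates, were 0.960 to 0.982.

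The tests of genes and lists, the gene lists and the rule for named genes were fixed before the data were examined. Genes were filtered with filterByExpr by group (minimum count 10), which left 18104, and were normalised by the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. A quasi-likelihood fit with 4 group means (4 residual degrees of freedom) gave the KO effect in males, the KO effect in females, the female effect minus the male effect (sex-by-genotype difference), and the sex difference in WT. An additive fit of sex and genotype (5 residual degrees of freedom) gave the genotype and the sex effect over both. Log2 fold changes are KO minus WT or female minus male. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Adjusted p-values are Benjamini-Hochberg values over the 18104 genes unless they are said to be adjusted over the list alone, and the threshold was 0.05. The estimated dispersion corresponds to a biological coefficient of variation of 27.8%, and the median SE was 0.32 in each sex and 0.26 over both. All tests are two-sided.

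Gene lists, 36 in all, covered skeletal development, the disc, the Pax1 neighbourhood, signalling, muscle, nervous tissue, blood, fat, vessels, skin, neighbouring organs, sex, stress, Hox genes and the mitochondrial genome. They were tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 36 lists. The same test with a correlation estimated per list, and fry, which asks whether a list moves on balance one way, were run as alternatives. List means per library, relative to the mean of the 8 libraries, were compared 4 against 4 by an exact permutation test over 70 assignments, whose smallest possible p is 0.0286. This comparison of list means was not among the tests fixed in advance. Its assignments also exchanged libraries between the sexes. With 2 libraries against 2 such a test cannot go below 0.333, so no permutation p is given within a sex.

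The genes named were set by rule. For each genotype comparison these were Pax1 and its tested neighbours, then, among genes past the threshold with no overlap between the genotypes and a mean of at least 1 CPM, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 genes passed, the 10 tested genes with the smallest p were named instead. For the sex-by-genotype difference the 10 genes with the smallest p among those that passed were to be named, or the 5 with the smallest p if none did. For sex, Xist, the Y-linked list and the 5 autosomal genes with the smallest p among those that passed were to be named. In each list described up to 4 members with the smallest p were named. Gene models without a proper name were counted but not named.

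The tests were tried on simulated counts drawn from the real genes' means and library sizes with 200 genes changed, in 3 runs. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of changes in lower genes was not measured. Each gene was drawn independently with its estimated spread, so shifts shared by many genes of a library were not simulated. Recovery in the real data can therefore be lower than the values given here. For the comparison in males (at least 17787 genes tested) 80% of 4-fold changes, 97.3% of 8-fold changes and 9.33% of 2-fold changes were recovered, with 31 false calls over the 3 runs. For females (at least 17809 genes) 79.3% of 4-fold changes and 11.3% of 2-fold changes were recovered, with 28 false calls. For both sexes (at least 17806 genes) 96.7% of 4-fold and 42.7% of 2-fold changes were recovered, with 27 false calls.

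Alternatives set in advance were size factors of the RLE type, DESeq2 1.42.0 on the same genes, no filter on low counts, leaving out each library in turn, the replicate number as a block, the skeletal muscle list mean as a covariate, a fit to the compared libraries only, the 4 group means in place of the additive fit, and a threshold of 1.5-fold. Added after the data were seen were the log2 mitochondrial share as a covariate, the fit without the pair of WT libraries richest in adipocyte transcripts (male WT 1 and female WT 2), limma voom with library quality weights, and crossed replicate numbers as a block in a fit to the 4 libraries of a sex. Figures were drawn with matplotlib 3.10.9.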

Results

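Whole spines from mouse embryos at E18.5 were compared between wild type (WT) and Pax1-Enh knockout (KO) animals of each sex by mRNA sequencing. The title of the series describes the deleted stretch as a sex-associated genomic region at Pax1 that is associated with adolescent idiopathic scoliosis. Pax1 encodes a transcription factor of the sclerotome, the embryonic source of vertebrae and discs. Each of the 4 groups held 2 libraries. Total counts were 48021848 and 47673931 in male WT, 38862212 and 35181518 in female WT, 67575728 and 59722279 in male KO, and 60557539 and 59834837 in female KO. Of 27179 genes counted, 18104 passed the filter on low counts and were tested.

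The first question was whether the deletion altered Pax1 itself. Pax1 (Entrez gene 18503, chromosome 2, 147361930 to 147375049 in mm10) was measured at 18.7 ± 2.42 CPM in male WT and 23.6 ± 6.60 CPM in male KO (SD, n = 2 each). In females the values were 22.8 ± 5.98 CPM in WT and 25.1 ± 7.41 CPM in KO (SD, n = 2 each). The log2 fold change was 0.34 in males (SE 0.31, adjusted p = 0.611), 0.14 in females (SE 0.31, adjusted p = 0.869) and 0.24 over both sexes (SE 0.22, adjusted p = 0.923), so no difference larger than the spread between libraries was detected. The 95% confidence interval of the fold was 0.769 to 2.07 in males, 0.671 to 1.81 in females and 0.833 to 1.67 over both. The female effect minus the male effect was -0.20 (SE 0.44, adjusted p = 0.8292). Leaving out 1 library at a time moved the Pax1 value in males between 0.02 (without male KO 1) and 0.60 (without male KO 2), and in females between -0.20 (without female KO 1) and 0.43 (without female WT 1). Over both sexes it moved between 0.09 (without male KO 1) and 0.39 (without female WT 1).

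**Figure D1:**
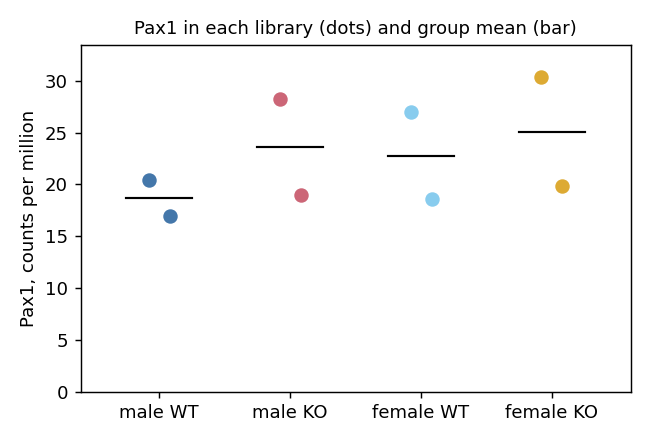
Pax1 in CPM (vertical axis) in each of the 8 libraries (dots), with the mean of each group of 2 (bar). The group means lie between 18.7 and 25.1 CPM, and the libraries of WT and KO overlap in both sexes.

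None of the 12 other tested genes around Pax1 passed the threshold, and the smallest adjusted p among them was 0.355 in males, 0.532 in females and 0.744 over both. Nkx2-2, a homeobox gene of the ventral neural tube 185 kb from Pax1, had log2 fold changes of -0.93 (SE 0.44) in males and 0.58 (SE 0.44) in females. Foxa2, a notochord and floor plate factor 681 kb away, had values of 0.32 (SE 0.31) and 0.45 (SE 0.31). Leaving out 1 library moved Nkx2-2 between -1.44 (without male KO 1) and -0.57 (without male KO 2) in males and between 0.23 (without female WT 2) and 1.04 (without female WT 1) in females. Foxa2 moved between 0.03 (without male KO 2) and 0.57 (without male KO 1) in males and between 0.24 (without female WT 2) and 0.67 (without female WT 1) in females. Of the others, Sstr4 had 1.17 (SE 0.63) in males and Ralgapa2 had -0.95 (SE 0.38) in females. The list of Pax1 and these neighbours was not called (mean log2 fold change 0.06 over both sexes, adjusted p = 0.361). In females fry gave it an adjusted p of 0.0262, although only 6 of the 12 neighbours were positive. The list mean, relative to the mean of the 8 libraries, was -0.0425 and -0.0255 in female WT and 0.00772 and 0.0685 in female KO.

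In males the comparison asked which genes and tissues differ in KO spines. Anterior Hox genes, which pattern the neck and upper trunk, fell by 1.09 on the log2 scale on average (12 of 13 negative, camera adjusted p = 1.261e-08; adjusted p = 0.340 with an estimated correlation). Posterior Hox genes, which pattern the lower trunk and tail, rose (mean log2 fold change 1.27, 13 of 15 positive, adjusted p = 1.187e-04; adjusted p = 0.499 with an estimated correlation). Hoxc5 had a log2 fold change of -2.54 (SE 0.29), Hoxc4 -1.58 (SE 0.22), Hoxa5 -1.59 (SE 0.30) and Hoxc6 -1.24 (SE 0.24). Hoxb13, a marker of the tail end of the axis, had 1 and 1 counts in male WT and 111 and 42 in male KO, a ratio of 49.2 with a counting interval of 13.4 to 410.3. No gene reached an adjusted p under 0.05 in edgeR (smallest 0.179), 2684 had an unadjusted p under 0.05 (1364 up, 1320 down) where 905.2 would be so by chance, DESeq2 called 487 (340 up, 147 down) and limma voom called 0. Adjusted over the list alone, 11 anterior Hox genes passed as lower, and of the posterior Hox genes 2 passed as higher and 1 as lower. Among the lists called in males, fry called anterior Hox, immediate early and matrix protease genes (adjusted p = 0.0413 each).

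**Figure D2:**
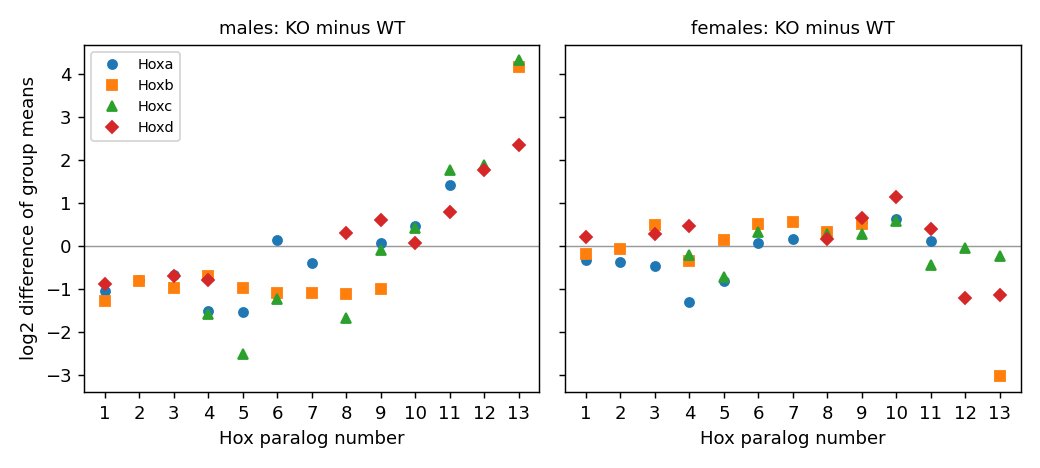
Log2 difference of KO and WT group means (vertical axis) for 38 Hox genes against their paralog number (horizontal axis), in males (left) and females (right). The slope per paralog number was 0.316 in males and -0.0228 in females, and the set of 38 genes was chosen after the list results were seen.

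The other genes with the smallest p in males, each at an adjusted p of 0.179 in edgeR and so not past the threshold there, had both signs. DESeq2 called each of those named here, with adjusted p from 1.750e-08 (Deptor) to 7.483e-06 (Arid5b and Rhcg). Deptor, an inhibitor of mTOR, had a log2 fold change of 2.21 (SE 0.28), and its mean was 4.63 CPM in male WT and 21.5 CPM in male KO. Fbxo32, a ubiquitin ligase of muscle atrophy, had 2.00 (SE 0.27), and Musk, the receptor kinase of the neuromuscular junction, had 2.07 (SE 0.30). Ppp1r12b had 1.78 (SE 0.25), Serpina3g 1.76 (SE 0.25) and Arid5b 1.63 (SE 0.24). Rhcg, an ammonium transporter, had -3.02 (SE 0.44).

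Across 17225 nuclear genes with a known transcript length, which are not independent replicates, the KO minus WT difference had a Spearman correlation with length of 0.287 in males and 0.159 in females. Skeletal muscle genes rose in male KO spines (mean log2 fold change 0.95, 28 of 29 positive, adjusted p = 1.261e-08; adjusted p = 0.525 with an estimated correlation), with Cacna1s at 1.52 (SE 0.34) and Myh7 at 1.68 (SE 0.45). Osteoclast genes rose by 0.73 on average (13 of 13 positive, adjusted p = 1.959e-06; adjusted p = 0.454 with an estimated correlation), among them Dcstamp at 0.92 (SE 0.21) and Mmp9 at 1.45 (SE 0.39). The list of immediate early and heat shock genes, which respond to acute stimuli and handling, rose by 0.87 (11 of 13 positive, adjusted p = 7.077e-07; adjusted p = 0.416 with an estimated correlation), with Fos at 1.73 (SE 0.29) and Fosb at 2.27 (SE 0.49). Its heat shock members, Hspa1a (-0.34, SE 0.34) and Hspa1b (-0.63, SE 0.38), were the 2 with negative values. Hedgehog pathway genes rose by 0.58 (11 of 12 positive, adjusted p = 2.692e-04; adjusted p = 0.499 with an estimated correlation), with Ptch1, a direct target of the pathway, at 1.42 (SE 0.40). In edgeR, 5 muscle, 6 osteoclast, 10 immediate early and 4 hedgehog genes of these lists passed adjusted over the list alone. All were higher, and 0 passed over all genes. DESeq2 called 7 muscle, 5 osteoclast, 6 immediate early and 2 hedgehog genes over all genes, all as higher. The muscle mean was 0.37 without male WT 2 and 1.54 without male WT 1, and the hedgehog mean was 0.39 without male KO 1.

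Cartilage genes rose in males by 0.49 (22 of 27 positive, adjusted p = 5.895e-04; adjusted p = 0.607 with an estimated correlation), with Chad at 1.22 (SE 0.36) and Comp at 1.53 (SE 0.50). Matrix proteases rose by 0.57 (adjusted p = 2.692e-04; adjusted p = 0.340 with an estimated correlation) and annulus fibrosus and tendon genes by 0.48 (adjusted p = 7.923e-04; adjusted p = 0.508 with an estimated correlation). Osteoblast genes rose by 0.39 (adjusted p = 0.0105; adjusted p = 0.525 with an estimated correlation). Of these 4 lists, 1 annulus and tendon gene, Egr1 (1.16, SE 0.28), passed adjusted over the list alone. Without male WT 2 the annulus and tendon mean was 0.23, and without male WT 1 it was 0.73. The osteoblast call ended without male KO 1 (0.27) and without male WT 2 (0.19), and the mean was 0.60 without male WT 1. With the mitochondrial share as a covariate the osteoblast call also ended (0.24, adjusted p = 0.0770) and the cartilage mean was 0.27.

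Endothelial and white blood cell lists were also called in males, while erythroid genes were not (mean -0.24, adjusted p = 0.838). Endothelial genes rose by 0.55 (adjusted p = 0.00631; adjusted p = 0.607 with an estimated correlation), neutrophil genes by 0.53 (adjusted p = 0.0112; adjusted p = 0.607 with an estimated correlation), macrophage genes by 0.28 (adjusted p = 0.0397; adjusted p = 0.607 with an estimated correlation) and inflammation genes by 0.67 (adjusted p = 0.00648; adjusted p = 0.454 with an estimated correlation). The neutrophil genes Ltf (1.75, SE 0.41) and Ngp (1.21, SE 0.32) passed adjusted over the list alone and no gene of the other 3 lists did. The endothelial call ended without male KO 1 (0.34) and male WT 2 (0.22), with a mean of 0.88 without male WT 1, and also with the mitochondrial share as a covariate (0.38, adjusted p = 0.0568). The neutrophil call ended without male KO 2 (0.39) and male WT 2 (0.24), with 0.82 without male WT 1. The macrophage call ended without male KO 1 (0.28), male KO 2 (0.29) and male WT 2 (0.17), and the inflammation call ended without male KO 2 (0.65), with 1.02 without male KO 1.

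Adipocyte genes fell by 1.80 on average in males (16 of 18 negative, adjusted p = 0.00360; adjusted p = 0.675 with an estimated correlation). The levels of Ucp1, the uncoupling protein of brown fat, were 419.6 and 49.6 CPM in male WT and 10.3 and 2.06 CPM in male KO. The call ended without male WT 1 (-0.69) and without male KO 2 (-1.41), and the mean was -2.91 without male WT 2. Lung genes fell by 1.96 (7 of 8 negative, 6 passing as lower adjusted over the list alone, adjusted p = 8.300e-04; adjusted p = 0.499 with an estimated correlation). The surfactant gene Sftpc was at 23.6 and 1.66 CPM in male WT and at 0.392 and 0.836 CPM in male KO. Mitochondrial genes fell by 1.60 (12 of 13 negative, adjusted p = 0.00137; adjusted p = 0.607 with an estimated correlation), in libraries whose mitochondrial share of counts was 17.5% and 19.6% in male WT and 4.34% and 15.01% in male KO. That call ended without male KO 1 (-0.54), and the mean was -2.65 without male KO 2. Of the adipocyte genes 0 and of the mitochondrial genes 1 (mt-Co3, -2.86, SE 0.65) passed adjusted over the list alone.

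In females the same question was asked. Adipocyte genes fell by 2.87 on average in KO spines (18 of 18 negative, adjusted p = 3.367e-11; adjusted p = 0.745 with an estimated correlation). Adiponectin (Adipoq) had a log2 fold change of -4.23 (SE 0.91), hormone-sensitive lipase (Lipe) -4.46 (SE 1.05), Cidec -5.68 (SE 1.39) and Pparg, the regulator of fat cell differentiation, -3.15 (SE 0.78). Ucp1 was at 31.7 and 889 CPM in female WT and at 1.45 and 7.62 CPM in female KO. Cartilage genes rose by 0.63 (25 of 27 positive, adjusted p = 2.172e-06; adjusted p = 0.745 with an estimated correlation), with lubricin (Prg4) at 1.29 (SE 0.25), Matn3 at 1.18 (SE 0.29) and Ucma at 1.17 (SE 0.31). Osteoblast genes rose by 0.41 (17 of 19 positive, adjusted p = 0.00607; adjusted p = 0.745 with an estimated correlation), with the osteocyte genes Dmp1 at 1.11 (SE 0.23) and Phex at 1.12 (SE 0.29). Without female WT 2, the library highest in adipocyte transcripts, the adipocyte mean was -1.66 and the cartilage mean was 0.27, and without female WT 1 the cartilage mean was 0.97.

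No gene passed in females in edgeR (smallest adjusted p 0.532), 1679 had an unadjusted p under 0.05, DESeq2 called 144 (24 up, 120 down) and limma voom called 0. The 120 include pancreatic enzyme genes, looked for after the values were seen, such as Pnliprp1 (-13.96, DESeq2 adjusted p = 2.736e-06), Cela2a, Clps and Cpa1. Pancreatic Ctrb1 was at 473 CPM in female WT 1 and 0.887 CPM in female WT 2. Pancreas taken with 1 spine was not tested as a source of these calls. Adjusted over the list alone, 12 adipocyte genes passed as lower, and 3 cartilage and 2 osteoblast genes as higher. The edgeR count was 33 without female WT 2. The genes with the smallest p in edgeR, none of them past the threshold there, included Itgbl1 (1.28, SE 0.24), the astrocyte water channel Aqp4 (1.54, SE 0.32), the lncRNA Miat (1.27, SE 0.27) and the sodium channel Scn9a (1.04, SE 0.22). Values were negative for mt-Co3 (-3.45, SE 0.67), the adipocyte galectin Lgals12 (-4.31, SE 0.84) and Fam83a (-2.99, SE 0.62). In DESeq2 adjusted p was 7.909e-07 for Lgals12, 3.109e-06 for mt-Co3, 0.00182 for Fam83a, 0.00626 for Aqp4 and 0.00717 for Itgbl1. Hoxb13 had 15 and 30 counts in female WT and 2 and 2 in female KO, a WT to KO ratio of 17.6 with a counting interval of 6.43 to 67.5, opposite in sign to males.

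Neuron genes rose in female KO by 0.39 (18 of 23 positive, adjusted p = 0.00176; adjusted p = 0.745 with an estimated correlation), with Elavl4 at 1.06 (SE 0.27), Slc17a6 at 0.95 (SE 0.30), Gad2 at 1.11 (SE 0.36) and Map2 at 1.07 (SE 0.35). Skeletal muscle genes rose by 0.46 (21 of 29 positive, adjusted p = 0.0255; adjusted p = 0.818 with an estimated correlation), with Neb at 1.48 (SE 0.34), Ttn at 1.52 (SE 0.41) and Myh2 at 1.85 (SE 0.51). Endothelial genes fell by 0.46 (9 of 10 negative, adjusted p = 0.0131; adjusted p = 0.745 with an estimated correlation) and cell cycle genes fell by 0.28 (15 of 18 negative, adjusted p = 0.00874; adjusted p = 0.745 with an estimated correlation). No member of these 4 lists passed adjusted over the list alone. These values stand beside a correlation of the female difference with transcript length of 0.159 across genes. The neuron call ended without female KO 2 (0.21), and the muscle call without female KO 1 (0.35), female WT 1 (0.27), male KO 1 (0.46) or male KO 2 (0.46). The endothelial call ended without female WT 2 (-0.24) and without the pair of WT libraries richest in adipocyte transcripts, male WT 1 and female WT 2 (-0.24, adjusted p = 0.160), with -0.70 without female WT 1. With the mitochondrial share as a covariate the muscle call ended (0.44, adjusted p = 0.0502). The cell cycle call ended without female KO 2 (-0.22) or female WT 1 (-0.14), with -0.43 without female WT 2.

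Over both sexes, with 4 libraries per genotype, several skeletal lists were called. Cartilage genes rose by 0.56 (27 of 27 positive, adjusted p = 9.061e-12), osteoblast genes by 0.40 (18 of 19, adjusted p = 4.886e-06), osteoclast genes by 0.46 (13 of 13, adjusted p = 5.317e-07), annulus fibrosus and tendon genes by 0.44 (17 of 17, adjusted p = 3.280e-06), matrix proteases by 0.36 (12 of 13, adjusted p = 7.671e-05) and skeletal muscle genes by 0.70 (27 of 29, adjusted p = 7.950e-12). Each of these 6 lists had an adjusted p = 0.275 with an estimated correlation. The collagenase Mmp13 had a log2 fold change of 1.01 (SE 0.28), aggrecan (Acan) 1.21 (SE 0.40), the osteocyte gene Mepe 0.99 (SE 0.22), Dcstamp 0.72 (SE 0.17) and the fast myosin Myh2 1.64 (SE 0.35). Genes associated with idiopathic scoliosis rose by 0.26 (15 of 19 positive, adjusted p = 0.00136; adjusted p = 0.275 with an estimated correlation), with Adgrg6, an adhesion receptor of cartilage and glia, at 0.70 (SE 0.18), and that call ended without male KO 1 (0.21). The scoliosis list was called in neither sex alone, and DESeq2 called 0 of its 19 genes in males, females or both sexes. Mepe, Dcstamp and Myh2 passed adjusted over the list alone, and the muscle mean was 0.42 without male WT 2. In females alone osteoclast genes (mean 0.19, adjusted p = 0.251), matrix proteases (0.14, adjusted p = 0.425) and annulus and tendon genes (0.40, adjusted p = 0.0783) were not called.

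Adipocyte genes fell by 2.34 over both sexes (18 of 18 negative, adjusted p = 1.002e-13; adjusted p = 0.275 with an estimated correlation) and anterior Hox genes by 0.60 (12 of 13 negative, adjusted p = 8.555e-07; adjusted p = 0.284 with an estimated correlation). Posterior Hox genes rose by 0.59 (14 of 15 positive, adjusted p = 4.098e-05; adjusted p = 0.275 with an estimated correlation), with a mean of 0.32 without male WT 1. In females alone neither Hox list was called: the anterior mean was -0.12 (7 of 13 positive, adjusted p = 0.509) and the posterior mean -0.08 (9 of 15 positive, adjusted p = 0.501). Without the pair of fat-rich WT libraries the mean over both sexes was -1.16 for adipocyte genes and 0.39 for posterior Hox genes, and both lists were still called. The genes with the smallest p in edgeR, none of them past the threshold there, included Adipoq (-3.65, SE 0.65) and Cidea (-4.36, SE 0.80) of the adipocyte list, and Lgals12 (-3.71, SE 0.61), Acvr1c (-3.10, SE 0.52), Lncbate10 (-5.90, SE 1.02), Ces1d (-5.06, SE 0.90) and Itpka (-3.87, SE 0.68). Ces1f, with 27, 8, 10 and 24 counts in WT and 3, 1, 1 and 0 in KO, was also among them, as were Hoxa4 (-1.46, SE 0.24) and mt-Co3 (-3.16, SE 0.46). DESeq2 called each of these genes, with adjusted p from 3.003e-09 (mt-Co3) to 0.00109 (Ces1f). Of the 50-base stretches of mt-Co3, 99.9% also occur in the transcript of another gene model, so its count depends on how shared reads were assigned. No gene passed in edgeR (smallest adjusted p 0.454), 1237 had an unadjusted p under 0.05, DESeq2 called 141 (29 up, 112 down) and limma voom called 0. Adjusted over the list alone, 13 adipocyte genes and 5 anterior Hox genes passed as lower, and no posterior Hox gene passed.

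Of the 36 lists, 7 had all 4 KO libraries on one side of all 4 WT libraries (1.03 would by chance): cartilage, osteoblast, osteoclast, matrix protease and idiopathic scoliosis genes were higher and adipocyte and anterior Hox genes lower in KO. Some genes, such as Mmp9 and Mmp13, belong to more than 1 list. Each of the 7 lists had an exact permutation p of 0.0286, the smallest possible, and 0.147 after adjustment over the 36 lists. All KO libraries were also deeper than all WT libraries, so these lists separate depth as well. The gap was small for anterior Hox genes (-0.00622 in female KO 1, 0.0377 in female WT 2). It was also small for scoliosis genes (0.0257 in female KO 1, -0.0213 in female WT 1). The mean adipocyte level was 1.17 ± 1.45 in WT and -1.17 ± 0.33 in KO (SD, n = 4 each, log2 relative to the mean of all libraries). WT levels were 1.81 and -0.40 in males and 0.41 and 2.85 in females.

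**Figure D3:**
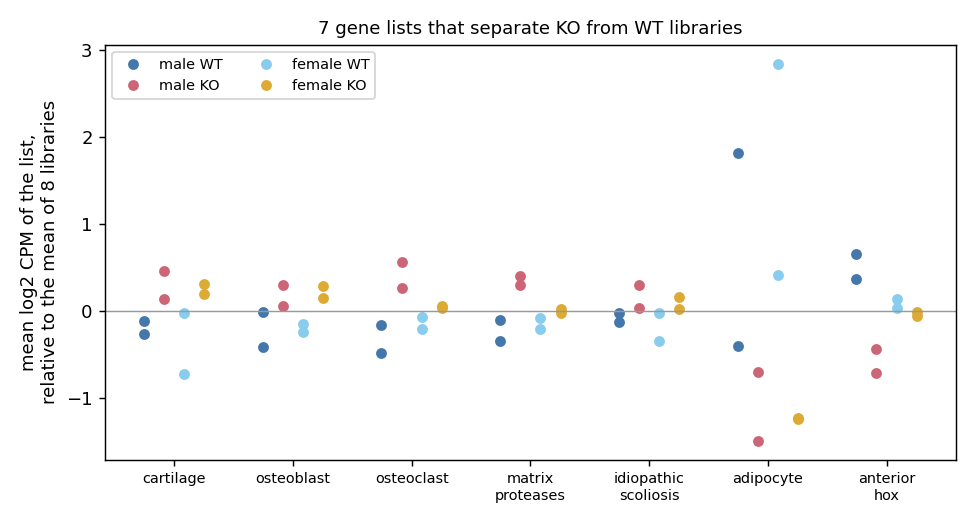
Mean log2 CPM of the genes of each list relative to the mean of the 8 libraries (vertical axis), 1 dot per library, for the 7 lists that separate KO from WT libraries. Adipocyte levels run from -0.40 to 2.85 in WT and from -1.49 to -0.70 in KO.

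A further 8 lists were called over both sexes. Hypertrophic chondrocyte genes rose by 0.28 (adjusted p = 0.0276; adjusted p = 0.275 with an estimated correlation), and interferon genes by 0.47 (adjusted p = 0.00104; adjusted p = 0.490 with an estimated correlation), hedgehog genes by 0.33 (adjusted p = 8.158e-04; adjusted p = 0.394 with an estimated correlation) and the immediate early and heat shock list by 0.33 (adjusted p = 0.00938; adjusted p = 0.523 with an estimated correlation). Inflammation genes rose by 0.27 (adjusted p = 0.0393; adjusted p = 0.420 with an estimated correlation) and glial genes by 0.13 (adjusted p = 0.0384; adjusted p = 0.302 with an estimated correlation). Adrenal and gonad steroidogenic genes fell by 1.19 (adjusted p = 0.0449; adjusted p = 0.538 with an estimated correlation) and mitochondrial genes by 0.80 (adjusted p = 0.0117; adjusted p = 0.565 with an estimated correlation), although 5 of 13 mitochondrial genes were positive. Adrenal Cyp11b1 was at 97.8 CPM in male WT 2, 49.1 CPM in female WT 1 and 95.7 CPM in female KO 2, and under 1 CPM in the other 5 libraries. Adjusted over the list alone, only mt-Co3 passed among these 8 lists.

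Each of these calls ended when certain single libraries were left out. The hypertrophic call ended without male WT 2 (0.29), female WT 2 (0.22), male KO 1 (0.27) or female KO 1 (0.23), the interferon call without male WT 2 (0.33) or female WT 1 (0.24), and the hedgehog call without male KO 1 (0.20). The immediate early call ended without male WT 1 (0.26), male WT 2 (0.18), male KO 1 (0.23) or male KO 2 (0.21), and the inflammation call without the same 4 libraries (0.26, 0.28, 0.33 and 0.18). The glial call ended without male WT 1 (0.13), female WT 1 (0.15), female WT 2 (0.10), male KO 1 (0.09), female KO 1 (0.13) or female KO 2 (0.11). The adrenal call ended without male WT 2 (-0.00394), female WT 1 (-0.50), male KO 1 (-0.75), male KO 2 (-0.95) or female KO 1 (-0.30), and the mitochondrial call without male WT 2 (-0.55) or male KO 1 (-0.22). Means moved further from 0 as well, with inflammation at 0.58 without female WT 2 and 0.56 without female KO 2, immediate early genes at 0.52 without female WT 2, glial genes at 0.22 without male KO 2, adrenal genes at -2.41 without female KO 2 and -2.01 without female WT 2, and mitochondrial genes at -1.30 without female KO 1. The interferon mean was 0.29 without female KO 1, and the call was kept. With the mitochondrial share as a covariate the glial (adjusted p = 0.151), immediate early (adjusted p = 0.117) and inflammation (adjusted p = 0.0830) calls ended. The mitochondrial call also ended over both sexes (-0.32, adjusted p = 0.638) and in males (-0.20, adjusted p = 0.942). That says nothing of its stability, since the covariate is made from the same genes. Without both fat-rich WT libraries the hypertrophic (adjusted p = 0.294) and glial (adjusted p = 0.276) calls ended, and the means were -3.04 for adrenal, 0.97 for interferon and 0.51 for inflammation genes. The glial call also ended without the low-count filter (adjusted p = 0.0534).

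The remaining lists were not called over both sexes. Sclerotome and segmentation genes, which include Pax1, had a mean of -0.03 (adjusted p = 0.806) and notochord and nucleus pulposus genes 0.07 (adjusted p = 0.315). Neuron genes had 0.08 (adjusted p = 0.277), erythroid genes -0.19 (adjusted p = 0.352), neutrophil genes 0.10 (adjusted p = 0.352), macrophage genes 0.04 (adjusted p = 0.536) and endothelial genes 0.04 (adjusted p = 0.753). Keratinocyte genes had -0.22 (adjusted p = 0.283), liver genes -0.43 (adjusted p = 0.283), lung genes -0.48 (adjusted p = 0.237), kidney genes 0.16 (adjusted p = 0.365) and cell cycle genes -0.05 (adjusted p = 0.565). Wnt target genes had 0.11 (adjusted p = 0.251) and BMP and TGF-beta genes 0.09 (adjusted p = 0.250), with Ccn2, a matricellular target of TGF-beta, at 1.10 (SE 0.27) and alone in passing adjusted over its list. Sex steroid receptor genes had 0.21 (adjusted p = 0.335), Y-linked genes 0.60 (adjusted p = 0.356) and X inactivation genes 0.25 (adjusted p = 0.193). Liver transcripts differed between libraries within groups, with Alb at 572 CPM in male KO 1 and 58.8 CPM in male KO 2.

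Whether the KO effect differed between the sexes was tested as the female effect minus the male effect. This difference contains the one between female and male WT. In WT, mitochondrial share was 17.5% and 19.6% in males and 5.29% and 7.01% in females. The values below therefore cannot be assigned to the deletion alone. Anterior Hox genes had a female effect minus male effect of 0.97 (13 of 13 positive, adjusted p = 1.667e-04), and the list of immediate early and heat shock genes of -1.09 (11 of 13 negative, adjusted p = 2.374e-05), each with an adjusted p = 0.807 with an estimated correlation. The heat shock genes Hspa1a (0.77, SE 0.48) and Hspa1b (0.58, SE 0.54) were the 2 positive members of that list. Camera called 13 lists (4 up, 9 down), and the estimated correlation left 0 of them. No gene passed in edgeR (smallest adjusted p 0.243), 3031 had an unadjusted p under 0.05, DESeq2 called 361 (198 up, 163 down), limma voom called 0, and the edgeR count was 9 without female WT 2. The genes with the smallest p were Hoxb13 (-9.51, SE 1.09), Deptor (-2.46, SE 0.38), Arid5b (-1.95, SE 0.33), Ago2 (-2.08, SE 0.36) and the neuronal RNA-binding gene Elavl4 (2.15, SE 0.38). The Hoxb13 value rests on 1 and 1 counts in male WT and 2 and 2 in female KO. Across the 18104 genes, which are not independent replicates, male and female effects had a Pearson correlation of -0.109 and a Spearman correlation of -0.246, and 40.0% of genes had the same sign. The exact p over 36 label assignments was 0.778, where 0.0556 is the smallest this design allows, and r ranged from -0.23 to 0.09 when 1 library was left out.

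Sex differences served to check the labels and to compare male with female libraries. In WT, sex went with mitochondrial share, which was 17.5% and 19.6% in males and 5.29% and 7.01% in females. Counts of genes by sex in WT therefore cannot be assigned to sex alone. With the log2 mitochondrial share as a covariate, edgeR called 38 genes by sex in WT. Xist, the RNA of the inactive X chromosome, had 13115 and 10705 counts in female WT, 40397 and 27023 in female KO, 11 and 72 in male WT, and 116 and 45 in male KO. Kdm5d, a Y-linked histone demethylase, had 821 and 887 counts in male WT, 1266 and 1286 in male KO and 1 in each female library. Ddx3y had 5479 and 10191 counts in male WT and 97 and 10 in female KO, and Eif2s3y 2865 and 3056 against 39 and 3. Female KO 1 held 158 counts from the Y-linked list in all. In WT, 1 gene passed in edgeR (Kdm5d, adjusted p = 1.151e-04), and Xist had a log2 fold change of 8.25 (SE 0.85, adjusted p = 0.0510). Over both genotypes 3 genes passed: Kdm5d (adjusted p = 1.516e-06), Xist (8.57, SE 0.61, adjusted p = 0.00133) and Uty (adjusted p = 0.0268), and no autosomal gene did. The WT count changed with the libraries kept: it was 1735 without male KO 1, 1671 without male KO 2, 30 without female WT 2 and 5 without either female KO library. DESeq2 called 2099 genes in WT and limma voom 2102, and over both genotypes these tools called 235 and 864, while the edgeR count there was 35 without male KO 2.

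Mitochondrial mRNAs, by which the labels do not group the libraries, divided the libraries otherwise than sex or genotype. Their share of counts was 17.5% and 19.6% in male WT, 5.29% and 7.01% in female WT, 4.34% and 15.01% in male KO, and 13.2% and 4.51% in female KO. The ratio between replicates was 1.12 in male WT, 1.32 in female WT, 3.46 in male KO and 2.93 in female KO. The size of these shares and the means of the mitochondrial list depend on how shared reads were assigned. Other gene models hold 100% of the 50-base stretches of mt-Co2, 99.5% of mt-Atp6, 98.8% of mt-Nd4l, 98.0% of mt-Nd3, 62.2% of mt-Nd4 and 51.1% of mt-Co1. They hold 0% of mt-Cytb, mt-Nd1, mt-Nd6 and mt-Atp8. WT counts of mt-Cytb were 2248332 and 2831779 in males and 516025 and 610148 in females. KO counts of mt-Cytb were 638512 and 1847769 in males and 1960023 and 585661 in females. The division of the libraries therefore does not rest on shared reads alone.

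**Figure D4:**
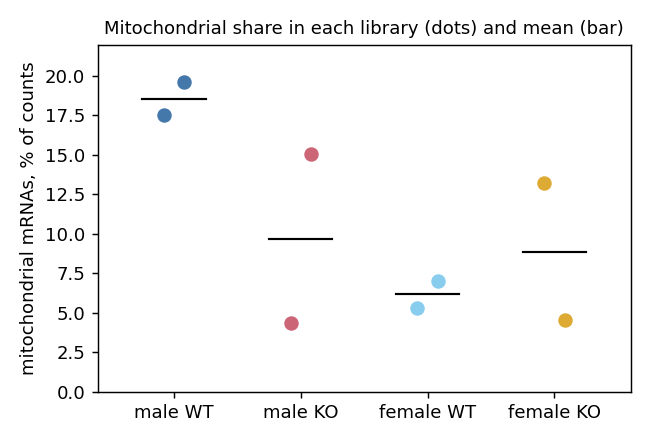
Share of counts from mitochondrial genes in percent (vertical axis) in each of the 8 libraries (dots), with the mean of each group of 2 (bar). Male KO and female KO each hold 1 library under 5% and 1 library of at least 13.2%.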

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

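Of the tests in this part, those on axial extent, on uneven fat, on the order of depths and on replicate ratios were chosen after the results were seen, as were the counts of genes over other splits of the samples.

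In males the Hox genes shifted with axial position: the slope of the log2 difference on paralog number was 0.316 over 38 genes, and anterior Hox genes were lower and posterior ones higher in KO. The slope was 0.319 after every library was thinned to the smallest. Thinning keeps each gene's expected share, so a slope over 38 genes would stay near its size either way. It therefore gives no verdict on counting noise or on other differences that go with depth. Depth follows genotype in these libraries. Uneven axial extent of the tissue, such as a spine taken longer or shorter at one end, cannot be told apart from an effect of the deletion: the largest slope within a replicate pair was 0.103 (male WT), between the bounds set for the test, and Hoxb13 also differed within females in the opposite direction. The slope between female WT and male WT, where no deletion is involved, was 0.195. An effect of the deletion on axial patterning in males stays open and untested.

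Adipocyte genes were lower in all 4 KO libraries, by 2.34 on the log2 scale on average. The gap was -2.36 after every library was thinned to the smallest. Thinning keeps each gene's expected share, so the gap would stay near its size either way. It gives no verdict on counting noise, and other differences that go with depth were not tested. Uneven fat taken with the spine is a candidate explanation: the list mean ranged over 3.25 within the WT libraries, more than the gap, against 0.790 within KO. Without the pair of fat-rich WT libraries, which were picked for being highest in this list, the call was kept over both sexes (mean -1.16) and in females (-1.66) and ended in males (-0.65, adjusted p = 0.149). An effect of the deletion on fat was not separated from this and stays open.

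The libraries divided in mitochondrial share in a way that sex and genotype do not follow. Sex or genotype alone is argued against by a ratio of 3.46 between the replicates of male KO, and library size by the depth of male KO 1, which at 67575728 counts was the deepest library and the lowest in share, while the shallow female WT libraries were also low. RNA or library quality may contribute, but the test cannot tell it from uneven tissue content of the libraries. The difference between the KO replicates, higher minus lower mitochondrial share, was correlated with male WT minus female WT across 18089 nuclear genes. The r was 0.421 in males and 0.303 in females, the latter only just past the bound of 0.3 set for it. Anything that goes with the share could give such values. The 2 KO pairs correlated with each other at 0.529, but their Spearman correlations with transcript length, -0.185 in males and -0.382 in females, were nearly absent from male WT minus female WT (-0.0680), so the likeness is partial, and genes are not independent replicates. A biological difference between embryos was not tested.

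Other splits of the 8 libraries, 4 against 4, were run as a test of chance. The 7 lists that fully separate the genotypes were matched by 1 of 35 splits, the real one, and the highest other split gave 3. That is the smallest share these splits allow, for a count not fixed in advance. No single list passes after adjustment (exact permutation, adjusted p = 0.147). The splits also exchange libraries between the sexes, although each sex holds 2 libraries per genotype. With labels exchanged only within each sex, the smallest share is 0.0556. Chance is therefore not excluded, for the count or for any 1 list. The real split also divides the deeper from the shallower libraries, so it cannot tell genotype from depth. For the 18 lists called over both sexes, 4 of 34 splits gave as many, the real one included, and the highest other gave 21, so chance cannot be excluded. For genes by genotype the real value was 0, so all 34 of 34 splits gave as many and the comparison is uninformative, and the highest other gave 1244. For genes by sex, 2 of 34 splits gave at least 3, the real one and the split with 3650. The split with the most genes was in both cases the 4 libraries of highest mitochondrial share (male WT 1, male WT 2, male KO 2 and female KO 1), which points to a structure of the samples.

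Among 74 values tested for a library far from the rest of its genotype, 3 passed the 95% critical ratio of gap to range, where chance gives 3.7. Sclerotome genes in female WT 1 stood at 0.28 against a mean of -0.07 in the other WT libraries (ratio 0.927). Inflammation genes in female WT 1 stood at -0.59 against 0.02 (ratio 0.859). Adrenal genes in female KO 2 stood at 3.02 against -1.80 in the other KO libraries (ratio 0.873).

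Camera called 13 lists for the sex-by-genotype difference, none of them with an estimated correlation (smallest adjusted p 0.807). Sex in WT went with mitochondrial share, so these values cannot be assigned to the deletion alone. The female effect minus the male effect was -0.55 for osteoclast, -0.49 for skeletal muscle, 0.61 for neuron, -0.86 for neutrophil, -0.49 for macrophage and -1.06 for adipocyte genes. It was -1.01 for endothelial, 2.95 for lung, -0.45 for cell cycle, -0.50 for hedgehog, -1.09 for immediate early, 0.97 for anterior Hox and 1.59 for mitochondrial genes. The heat shock members Hspa1a and Hspa1b were positive in the immediate early list.

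The immediate early, anterior Hox, endothelial and lung lists kept their call whichever library was left out, and the other 9 did not. The lung value rests on counts that were low in female WT and uneven in male WT. Sftpc had 956 and 72 counts in male WT, 7 and 7 in female WT, 30 and 45 in male KO, and 50 and 216 in female KO. Nkx2-1 had 20 and 5 counts in male WT and 0 and 0 in female WT. The osteoclast call ended without male WT 2 (-0.39), the neuron call without male KO 2 (0.38) or female KO 2 (0.40), the cell cycle call without female WT 1 (-0.33) or male KO 2 (-0.32), and the hedgehog call without male WT 1 (-0.49), female WT 1 (-0.37) or male KO 1 (-0.30). The neutrophil call ended without male WT 2 (-0.57), female WT 2 (-0.34), male KO 2 (-0.71) or female KO 2 (-0.77), and the macrophage call without the same 4 libraries (-0.37, -0.36, -0.49 and -0.32). The muscle value turned to 0.09 without male WT 2, and its call also ended without female WT 2 (-0.35), male KO 2 (-0.50) or female KO 2 (-0.41). The adipocyte value turned to 0.04 without male WT 2 and 0.12 without female WT 2, and its call also ended without male KO 1 (-0.67), male KO 2 (-1.46) or female KO 2 (-1.09). The mitochondrial call ended without male WT 2 (1.36), female WT 1 (1.18), male KO 1 (0.54) or female KO 1 (0.73).

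Other values moved away from 0 with the call kept. The neutrophil value was -1.44 and the adipocyte value -2.32 without female WT 1, the adipocyte value -2.17 and the muscle value -1.08 without male WT 1, and the mitochondrial value 2.64 without male KO 2 and 2.41 without female KO 2. With the mitochondrial share as a covariate the hedgehog (adjusted p = 0.179) and adipocyte (adjusted p = 0.0620) calls ended, and the neuron value was 1.00. Without the pair of fat-rich WT libraries the macrophage call ended (-0.50, adjusted p = 0.0775), and the muscle value was -0.97 and the cell cycle value -0.77. The adipocyte call also ended with RLE size factors (-1.11).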

How the results depend on the processing

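Alternatives with the mitochondrial share, the fat-rich libraries, voom and crossed replicate numbers were chosen after seeing the data. Except where said, the cause was not tested. DESeq2 called 487 genes in males, 144 in females, 141 over both sexes, 361 for the sex-by-genotype difference, 2099 by sex in WT and 235 by sex over both. Without a low-count filter the counts were 39 in males, 1 for the sex-by-genotype difference, 629 by sex in WT and 12 by sex over both. The replicate block gave 2 by sex in WT, and the muscle covariate 13 over both sexes, 1 for the sex-by-genotype difference, 3 by sex in WT and a reversed Nkx2-2 value over both of 0.52. A fit to the 4 WT libraries alone gave 1860 by sex, and 4 group means gave 5 by sex over both. An estimated correlation called 0 lists in males, 0 in females, 0 over both and 0 for the sex-by-genotype difference, and fry 3, 1, 0 and 0. The Spearman correlation of male and female effects was -0.246. The mitochondrial covariate gave 2 genes in females, 38 by sex in WT, 9 by sex over both and a reversed mitochondrial sex-by-genotype value of -0.21, which says nothing of stability since the covariate is made from the same genes. Without the 2 fat-rich WT libraries the counts were 24 genes and 11 lists in females, 1 gene for the sex-by-genotype difference and 4 by sex in WT, and Pax1 in females turned to -0.11. Voom gave 2102 by sex in WT, 864 by sex over both and a reversed Pax1 value over both of -0.050. A fit to the 4 female libraries alone with crossed replicate numbers as a block gave 6 in females, where those libraries without the block gave 0. The crossing goes against the labels' numbers and was picked from these same counts. In them the replicate deviations of female WT and female KO correlated at -0.144. The 6 calls are therefore no support for a change.

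Leaving out 1 library leaves a lone library in its group, assumed to vary like the other groups. Gene counts then ranged from 0 to 33 in females, 0 to 9 for the sex-by-genotype difference, 1 to 1735 by sex in WT and 2 to 35 by sex over both, and stayed at 0 in males and over both sexes. List counts ranged from 6 to 12 in females, 11 to 21 over both and 7 to 16 for the sex-by-genotype difference. Pax1 ranged from -0.20 to 0.43 in females and from -0.54 to 0.12 for the sex-by-genotype difference, Nkx2-2 over both from -0.48 to 0.14, the correlation from -0.23 to 0.091, and the sex-by-genotype value from -2.32 to 0.12 for adipocyte and from -1.08 to 0.087 for muscle genes. Among the other values of single genes, 413 kept their direction and side of the threshold, 83 came to pass it and 3 no longer passed, and with a library left out these were 407, 21 and 5. List values kept both in 260 cases and lost the call in 124, and with a library left out in 361 and 76. At 2 libraries per group a 2-fold change was recovered in 9.33% of simulated cases in males. After thinning to equal total counts, which does not equalise the depth over nuclear genes, 0 genes were called by edgeR in males, females or both.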

Other observations

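The genes in this part that no rule named were chosen after their values were seen. Ccn2 had log2 fold changes of 1.16 (SE 0.39) in males and 1.05 (SE 0.39) in females, Mepe 1.02 (SE 0.30) and 0.95 (SE 0.31), and Adgrg6 0.83 (SE 0.25) in females. Gdf5, a signal of joint formation, had -1.15 (SE 0.31) in females. None of these passed over all genes in edgeR.

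Glial genes of the male comparison went both ways: Erbb3, a neuregulin receptor of Schwann cells, had 1.49 (SE 0.34), while Fabp7, a gene of radial glia, had -2.17 (SE 0.63). In edgeR both passed adjusted over the list alone and not over all genes. DESeq2 called 2 genes of the glial list as higher and 1 as lower in males. Ctrb1, a pancreatic enzyme gene, was at 473 CPM in female WT 1 and at most 0.887 CPM in every other library.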
